A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

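Messenger RNA levels of budding yeast were compared on 9 Agilent 2-colour arrays, each hybridised with RNA of a mutant strain in one dye and RNA of a reference strain in the other. Per the labels' protocols, total RNA was isolated on a silica matrix, amplified linearly with an Agilent low-input kit and labelled with Cy3 or Cy5 from a Micromax kit. The K123R strain, the ubp8 deletion strain and the K123R ubp8 double mutant were each compared with wild type on 2 arrays of opposite dye. Array 1 of each pair carried the mutant in Cy5 and array 2 carried it in Cy3. The K123R strain was compared with an htb2 deletion strain on 3 arrays, with K123R in Cy5 on array 2 only. The series design calls the arrays biological replicates. Neither the labels nor the design text say whether the arrays shared a wild-type RNA sample.

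Per the file headers, spot intensity was read with Agilent Feature Extraction A.7.5.1 on the 6 arrays against wild type and 8.5.1.1 on the 3 arrays against the htb2 deletion strain. The scanner files hold, per spot and colour, the mean signal, the median local background, and a processed signal that the software had corrected for background and normalised between the dyes, per the file headers. The deposited series values are the log10 ratio of mutant over reference strain. They differed from log10 ratios recomputed from the dye-normalised signals of the scanner files by at most 5.0e-10, after the sign was turned on arrays with the mutant in Cy3.

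The values reported were computed from the unprocessed mean signals and median backgrounds in R 4.3.3 with limma 3.58.1. Background was corrected with the normexp method and an offset of 50, and each array was normalised by loess over its own spots. Control spots were left out. Spots marked by the scanner software as non-uniform or as population outliers in either colour were also left out, and saturated spots were kept. Each of the 6256 probes stands for 1 gene, and repeated spots of a probe were averaged on the log2 scale. Ratios were turned so that a positive value means more RNA in the mutant. A gene was tested if its probe was well above background in at least one colour on no fewer than 3 of the 6 arrays against wild type, or 2 of the 3 arrays against the htb2 deletion strain.

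Linear models were fitted in limma with empirical Bayes moderation, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, with a threshold of 0.05. The 6 arrays against wild type entered one fit with a mean per mutant, which leaves 3 residual degrees of freedom per gene. In it, 4 contrasts were also tested: the double mutant against each single mutant, K123R against ubp8, and the departure of the double mutant from the sum of the single mutants, called the interaction. These contrasts are indirect, through wild type. In this fit, the within-pair deviations of the 3 mutants correlated at 0.86 to 0.89 across genes. The 3 residual degrees of freedom are thus not independent, and the p-values of the fit and its contrasts are approximate. The 3 arrays against the htb2 deletion strain were fitted alone with a gene-specific dye term, because their dye orientations do not balance. This leaves 1 residual degree of freedom. For 410 genes tested there, the arrays with a value could not carry a dye term, and these were fitted by the mean alone.

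Gene lists were tested with camera at a preset correlation between genes of 0.01, two-sided, and adjusted over the 36 lists in each comparison. Each was tested again with a correlation estimated from the residuals, and with fry. Counts of list members that pass are given over all genes tested and adjusted over the list alone. The pathway, complex, gene family, mating-type and marker lists, the filter, the models, the rule for naming genes and the other settings tried were chosen before the data were examined. By that rule, HTB1, HTB2, UBP8, HTA1 and HTA2 are reported in each of the 4 direct comparisons. To these come the 10 highest and 10 lowest log2 ratios among genes with a gene name that passed with the same sign on every array, and up to 4 members with the smallest adjusted p of each list that was called or had at least 3 members passing. The text gives the values of part of the genes so named. For the 4 contrasts, the 5 highest and 5 lowest passing genes are named, or the 5 with the smallest p where none pass. Mating-type and auxotrophic marker genes serve as a check of genotype. Genes named outside the rule are said to be so. Of 6256 systematic gene names on the arrays, 5756 matched a locus tag of the RefSeq annotation of assembly R64, which supplied 5260 gene symbols and the order of neighbouring genes.

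The pipeline was tested on simulated data with 200 changed genes, under 2 models of the noise. The second model was added after the first had shown low recovery for K123R against the htb2 deletion strain. With each gene's own residual spread, 53.7% of genes changed by 0.5 on the log2 scale, 88.1% by 1 and 98.5% by 2 were recovered in K123R against wild type, among 6250 genes, with 7 other genes called. For the contrast of the double mutant with K123R the shares were 29.9%, 79.1% and 92.4%, with 7 others called. For the interaction they were 28.4%, 73.1% and 97.0%, with 7 others. For K123R against the htb2 deletion strain, among 6220 genes, the shares were 0%, 0% and 47.0%, with 0 others called. With variances drawn from the fitted prior, the last comparison gave 73.1%, 100% and 100%, with 27 others called. Under that model K123R against wild type gave 55.2%, 92.5% and 98.5%, with 7 others. A simulated shifted list was called and 0 of the other lists were. The simulated noise was independent between genes and arrays. It therefore does not show how the list test fares where members vary together, as in the histone list (estimated correlation 0.85). Nor do the shares recovered describe the real fit against wild type and its contrasts, where same-numbered arrays deviated together (0.86 to 0.89 across genes).

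The other settings chosen at that stage were no background subtraction, the Agilent processed signals, the deposited values, median centring in place of loess, no filter, a filter on both colours in every array, a trended and robust variance prior, leaving out each array in turn, the slide as a random block, and the array number as a block. Within the arrays against wild type the array number coincides with the dye orientation, so that block is a gene-specific dye term. Further ones were fits to only the 2 arrays of a comparison, and the fit against the htb2 deletion strain without its dye term. Keeping outlier-marked spots, leaving out saturated spots, and leaving out array 3 against the htb2 deletion strain for the gene lists were chosen after seeing the data, as was the histone list without HTB2. The number of arrays limits the precision of every value.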

Results

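Gene expression was measured in 5 strains of budding yeast that differ in histone H2B and in its deubiquitylation. The lysine K123 of H2B is the residue to which the enzymes Rad6 and Bre1 attach ubiquitin, and Ubp8, a subunit of the SAGA complex, removes it. In the K123R strain (CY1272) the only H2B gene is HTB1 with arginine in place of this lysine, and the second H2B gene, HTB2, is deleted. The other mutants lack UBP8 (BY10809), carry both changes (CY1383, the double mutant) or lack HTB2 alone (BY13026). The reference strain was BY4742, a wild type of mating type alpha. There were 2 arrays of opposite dye for each of K123R, ubp8 and the double mutant against wild type, and 3 arrays for K123R against the htb2 deletion strain. The arrays of the first kind carried 10807 spots and those of the second 10789, both for 6256 genes. The median signal was 25.8 to 54.6 times the median background in green and 43.3 to 65.4 times in red. On each array, 99.3% to 99.9% of spots were well above background in at least one colour and 1.71% to 2.49% were saturated. Spots marked as outliers made up 0.76% to 3.62% of the arrays against wild type and 18.8% to 19.0% of those against the htb2 deletion strain. Log2 ratios are given as mutant over reference strain with the standard error from limma.

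The targeted genes were first read on every array as a check of genotype. HTB2 (YBL002W) was lower in K123R than in wild type by −3.68 and −3.87 on the 2 arrays and by −3.16 and −3.64 in the double mutant. UBP8 (YMR223W) read −2.54 and −2.08 in the ubp8 deletion strain and −2.32 and −2.40 in the double mutant, against −0.28 and −0.12 in K123R. The K123R substitution does not remove the HTB1 message, whose ratio checks nothing here: it was 0.14 ± 0.18 in K123R against wild type (adjusted p = 0.643). HIS3 (YOR202W), a marker deleted in BY4742, rose by 3.17 ± 0.37 in K123R (adjusted p = 0.00685), by 2.86 ± 0.37 in the double mutant (adjusted p = 0.00954) and by 3.63 ± 0.09 in K123R against the htb2 deletion strain (adjusted p = 8.6e-05). It read −0.22 ± 0.37 in ubp8 (adjusted p = 0.821). LEU2 (YCL018W), another marker deleted in BY4742, rose by 3.70 ± 0.20 in K123R against wild type (adjusted p = 0.00237), with 4.12 and 3.27 on the 2 arrays. On those arrays its signal was 3163 and 3101 in K123R and 197 and 404 in wild type. LEU2 read −0.05 ± 0.20 in the double mutant (adjusted p = 0.897) and −0.21 ± 0.08 in K123R against the htb2 deletion strain (adjusted p = 0.104), where K123R signals were 124, 232 and 129. K123R RNA thus had a high LEU2 signal in one comparison and a low one in the other. URA3 and LYS2 did not pass in any direct comparison, and the 7 genes specific to mating type a had 0 members passing in each of the 4 by limma.

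**Figure D1:**
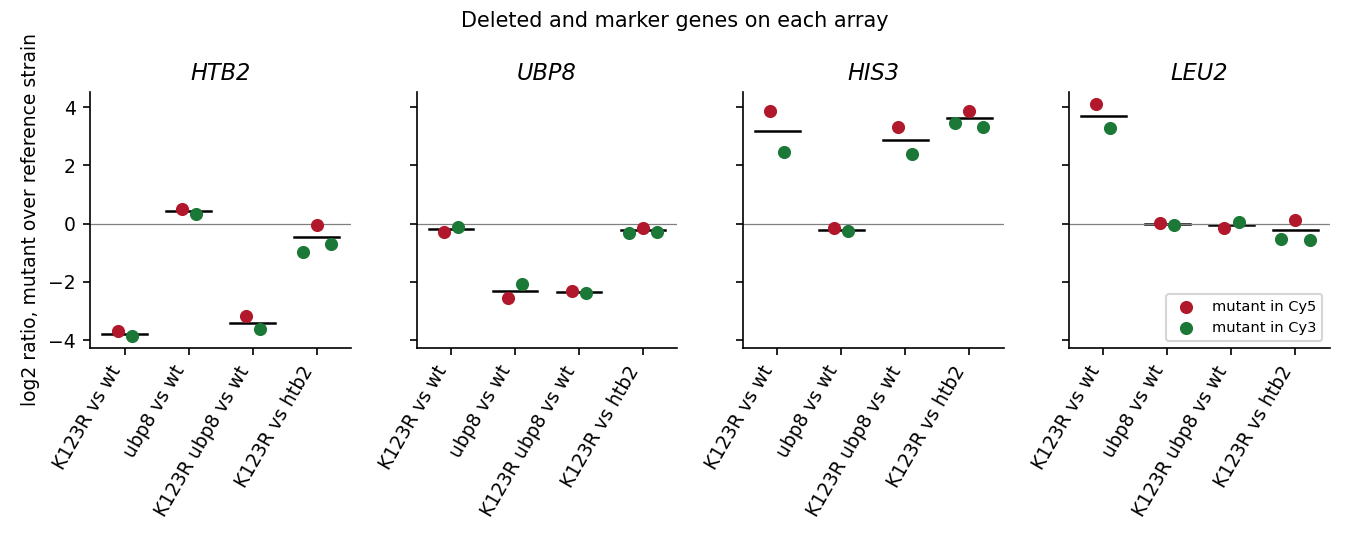
Log2 ratio of mutant over reference strain (y axis) for HTB2, UBP8, HIS3 and LEU2 in the 4 direct comparisons (x axis), with a point per array (red, mutant in Cy5; green, mutant in Cy3) and a bar at the fitted value. LEU2 read 4.12 and 3.27 in K123R against wild type and stayed between −0.56 and 0.14 on the other 7 arrays.

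K123R against wild type asks which genes respond when H2B can no longer be ubiquitylated, together with the loss of HTB2. The strains also differed in HIS3 and LEU2 signal, so responses to these markers cannot be told apart from responses to the lysine. Apart from the marker genes, the largest increases were in COS12 (3.05 ± 0.10, adjusted p = 9.1e-04), a member of a family found near chromosome ends. Next came the cell wall mannoprotein gene HPF1 (2.69 ± 0.08, adjusted p = 9.1e-04) and its sequence relative CSS1 (2.58 ± 0.14, adjusted p = 0.00237). ARG1 of arginine synthesis rose by 2.32 ± 0.11, the chitin deacetylase gene CDA1 by 2.05 ± 0.13 and SER3 of serine synthesis by 2.01 ± 0.24. The sporulation septin gene SPR28 rose by 1.70 ± 0.10 and SNZ1 of vitamin B6 synthesis by 1.57 ± 0.18. After HTB2, the largest decreases were in the cell wall protein gene CWP1 (−1.54 ± 0.21, adjusted p = 0.00932), PNS1 (−1.50 ± 0.15), PGM2, which encodes phosphoglucomutase (−1.28 ± 0.10), BDH2 (−1.20 ± 0.06) and the mitochondrial carrier gene DIC1 (−1.05 ± 0.07). In all, 686 genes rose and 632 fell among 6250 tested, 39 and 9 of them by at least 2-fold.

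Genes of ribosome assembly rose together in K123R. Of 74 tested, 50 rose and 0 fell (58 and 0 adjusted over the list alone), with a median of 0.38. Among them were DBP10 (0.62 ± 0.05), SPB1 (0.57 ± 0.05), ENP2 (0.50 ± 0.05) and RRP5 (0.47 ± 0.05). The camera adjusted p was 2.2e-19, and the adjusted p with an estimated correlation was 0.261. The 138 ribosomal protein genes were not called as a list (adjusted p = 0.941) and 2 of them rose. Of 39 genes of amino acid synthesis under Gcn4 control, 14 rose and 4 fell (14 and 4 adjusted over the list alone). They were led by ARG1, ARG3 (1.24 ± 0.06) and ARG5,6 (0.74 ± 0.05). Its camera adjusted p was 2.2e-05, and the adjusted p was 0.363 with an estimated correlation. Nitrogen catabolite genes also rose, 9 of 22 with 2 falling (10 and 2 adjusted over the list alone), among them the amino acid permease gene GAP1 (1.44 ± 0.10), DAL1 (0.72 ± 0.06) and CAR1 (0.71 ± 0.06). The camera adjusted p was 9.8e-04, and it was adjusted p = 0.477 with an estimated correlation. Thiamine and vitamin B6 genes rose in 9 of 19 cases with 0 falling (9 and 0 adjusted over the list alone), including SNZ2 (0.82 ± 0.07), THI12 (0.82 ± 0.08) and SNZ3 (0.71 ± 0.06). Their adjusted p was 4.2e-04, or adjusted p = 0.363 with an estimated correlation. Genes of oxidative phosphorylation rose in 11 of 35 cases (21 adjusted over the list alone), with ATP16 at 0.54 ± 0.05 and ATP14 at 0.43 ± 0.05, and 0 fell (camera adjusted p = 7.3e-04, adjusted p = 0.493 with an estimated correlation). Among 25 meiosis and sporulation genes 8 rose (9 up and 2 down adjusted over the list alone), with SPR3 at 0.81 ± 0.11 and SPS4 at 0.66 ± 0.07 beside SPR28 (camera adjusted p = 0.00522, adjusted p = 0.595 with an estimated correlation).

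Genes of the general stress response fell in K123R, 18 of 34 with 1 rising (26 and 3 adjusted over the list alone), with a median of −0.47. They include PGM2, the glycogen synthase gene GSY1, the catalase gene CTT1 (−0.89 ± 0.06), the glucokinase gene GLK1 (−0.75 ± 0.06) and GPD1 (−0.70 ± 0.05). The camera adjusted p was 1.4e-09, and the adjusted p was 0.363 with an estimated correlation. Phosphate starvation genes fell in 7 of 16 cases (9 adjusted over the list alone), with PHM8 at −0.83 ± 0.05, SPL2 at −0.81 ± 0.08, and VTC2 and VTC3, which make polyphosphate, both at −0.61 (camera adjusted p = 4.6e-05, adjusted p = 0.363 with an estimated correlation). Ergosterol genes fell in 4 of 21 cases with 1 rising (5 and 1 adjusted over the list alone), among them ERG5 (−0.48 ± 0.05) and ERG8 (−0.45 ± 0.05), with camera adjusted p = 0.0168 and adjusted p = 0.412 with an estimated correlation. Of the 4 alpha-specific genes the a-factor receptor gene STE3 (−0.87 ± 0.08) and the agglutinin gene SAG1 (−0.76 ± 0.05) fell, while MF(ALPHA)1 (−0.23 ± 0.10) and MF(ALPHA)2 (−0.20 ± 0.12) did not pass (camera adjusted p = 4.8e-04, adjusted p = 0.363 with an estimated correlation). Among 10 histone genes the deleted HTB2 alone passed, HTA1 read −0.08 ± 0.30 and HTA2 −0.21 ± 0.17. The list call (camera adjusted p = 0.00432, adjusted p = 0.75 with an estimated correlation) rests on HTB2. Without it, in a test added after the data were seen, the camera adjusted p was 0.569. The median of all 10 was 0.01 on array 1 and −0.48 on array 2. The count of 1318 genes was 34 without K123R array 1, 56 without K123R array 2 and 822 without either ubp8 array, and was 4137 with a gene-specific dye term.

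Deleting UBP8 changed fewer genes, 115 up and 60 down of 6246 tested, which addresses what follows when SAGA can no longer remove ubiquitin from H2B. After UBP8 itself (−2.31 ± 0.12, adjusted p = 0.0101), the largest decreases were in 2 phosphate-responsive genes, PHO89, a phosphate transporter (−1.91 ± 0.18, adjusted p = 0.0254), and PHO5, the secreted acid phosphatase (−1.51 ± 0.11, adjusted p = 0.0227). The glycine cleavage gene GCV1 (−0.84 ± 0.14), the glucose transporter gene HXT6 (−0.78 ± 0.09) and the hexokinase gene HXK1 (−0.78 ± 0.06) fell. So did ADE17 (−0.76 ± 0.08) and ADE1 (−0.72 ± 0.09) of purine synthesis. The largest increases were in COS12 (1.18 ± 0.10, adjusted p = 0.0241), the purine-cytosine permease relative FCY21 (1.05 ± 0.07, adjusted p = 0.0177), and the polyamine transporter gene TPO2 (0.99 ± 0.15). They were followed by CDA1 (0.96 ± 0.13), RSC30 (0.90 ± 0.07), the metallothionein genes CUP1-1 (0.89 ± 0.11) and CUP1-2 (0.88 ± 0.11), YAT1 (0.89 ± 0.05) and the zinc transporter gene ZRT1 (0.88 ± 0.12). HTB2 read 0.43 ± 0.13 (adjusted p = 0.136), HTB1 0.26 ± 0.18 (adjusted p = 0.499), HTA1 0.24 ± 0.30 (adjusted p = 0.719) and HTA2 0.33 ± 0.17 (adjusted p = 0.346).

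Of 13 purine synthesis genes, 3 fell in ubp8 (12 adjusted over the list alone), with a median of −0.58 that was −0.32 on array 1 and −0.85 on array 2 (camera adjusted p = 2.5e-11, adjusted p = 0.392 with an estimated correlation). Phosphate starvation genes fell in 2 of 16 cases, PHO5 and PHO89 (1 up and 5 down adjusted over the list alone), with camera adjusted p = 3.3e-05 and adjusted p = 0.371 with an estimated correlation. General stress genes fell in 6 of 34 cases (18 down and 3 up adjusted over the list alone), with HXK1, GSY1 (−0.73 ± 0.12), GPH1 (−0.60 ± 0.07) and HSP78 (−0.58 ± 0.07) among them. Their camera adjusted p was 1.8e-08, and the adjusted p was 0.392 with an estimated correlation. Sulfur and methionine genes fell in 2 of 25 cases (3 adjusted over the list alone), MET17 (−0.59 ± 0.06) and the methionine permease gene MUP1 (−0.47 ± 0.06), with camera adjusted p = 1.0e-04 and adjusted p = 0.392 with an estimated correlation. Ribosome assembly genes had a median of 0.19 with 4 of 74 rising (20 adjusted over the list alone), among them SPB1 (0.49 ± 0.05) and ENP2 (0.45 ± 0.05), with camera adjusted p = 1.8e-11 and adjusted p = 0.172 with an estimated correlation. Thiamine genes rose in 4 of 19 cases (12 adjusted over the list alone), with THI4 at 0.69 ± 0.06 and SNZ2 at 0.47 ± 0.07 (camera adjusted p = 1.7e-07, adjusted p = 0.172 with an estimated correlation). COS family genes rose in 3 of 12 cases (3 adjusted over the list alone), COS12, COS8 (0.71 ± 0.10) and COS7 (0.44 ± 0.05), with camera adjusted p = 4.6e-04 and adjusted p = 0.392 with an estimated correlation. Genes within 20 kb of a chromosome end rose in 17 of 244 cases and fell in 5 (30 and 9 adjusted over the list alone), with a median of 0.05, camera adjusted p = 0.00529 and adjusted p = 0.172 with an estimated correlation. The count of 175 was 8 without either K123R array, 0 without either double mutant array, 0 without ubp8 array 1 and 1 without ubp8 array 2. A fit to only the 2 ubp8 arrays gave 237 genes, 130 of them among the 175. The count was 91 from the Agilent processed signals, 85 from the deposited values and 3119 with a gene-specific dye term.

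The double mutant asks whether losing Ubp8 matters once K123 is gone, and its profile mostly followed that of K123R. The oxidative phosphorylation list, called in K123R, was not called in the double mutant (camera adjusted p = 0.211). Of its 35 genes, 4 rose and 1 fell (3 and 0 adjusted over the list alone). COS12 (2.98 ± 0.10, adjusted p = 0.00141), HPF1 (2.39 ± 0.08, adjusted p = 0.00141), CSS1 (2.33 ± 0.14), ARG1 (2.09 ± 0.15, from 1 array), CDA1 (2.01 ± 0.13), SER3 (1.88 ± 0.24) and SPR28 (1.46 ± 0.10) rose against wild type. After the deleted HTB2 and UBP8, PNS1 (−1.41 ± 0.15), CWP1 (−1.38 ± 0.21), PGM2 (−1.22 ± 0.10), BDH2 (−1.04 ± 0.06) and TGL2 (−0.99 ± 0.06) fell most. HTB1 read 0.07 ± 0.18 (adjusted p = 0.825), HTA1 −0.16 ± 0.30 (adjusted p = 0.764) and HTA2 −0.29 ± 0.17 (adjusted p = 0.282). There were 617 genes up and 626 down of 6246 tested, 32 and 6 of them by at least 2-fold. Ribosome assembly genes rose in 49 of 74 cases (58 adjusted over the list alone), with a median of 0.39, camera adjusted p = 3.7e-21 and adjusted p = 0.251 with an estimated correlation. Stress genes fell in 18 of 34 cases with 1 rising (21 and 2 adjusted over the list alone), with camera adjusted p = 3.3e-08 and adjusted p = 0.336 with an estimated correlation. Phosphate genes fell in 7 of 16 cases (9 adjusted over the list alone; camera adjusted p = 2.5e-06, adjusted p = 0.299 with an estimated correlation), with PHM8 at −0.80 ± 0.05 and SPL2 at −0.79 ± 0.08. Amino acid genes rose in 13 of 39 cases and fell in 2 (14 and 3 adjusted over the list alone; camera adjusted p = 1.3e-04, adjusted p = 0.299 with an estimated correlation). Iron genes fell in 7 of 24 cases (7 adjusted over the list alone), among them ARN2 (−0.60 ± 0.06), FRE3 (−0.59 ± 0.05) and MRS4 (−0.56 ± 0.07), with camera adjusted p = 0.0336 and adjusted p = 0.374 with an estimated correlation. Genes near chromosome ends rose in 41 of 243 cases and fell in 23 (44 and 24 adjusted over the list alone), with a median of 0.08, camera adjusted p = 0.0079 and adjusted p = 0.299 with an estimated correlation. The count of 1243 was 3 without either double mutant array, 742 without either K123R array and 823 without either ubp8 array, and 4083 with a gene-specific dye term.

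Across 6246 genes, which are not independent replicates, the log2 ratios of K123R and of the double mutant against wild type had Pearson r = 0.95 and Spearman rho = 0.94. Both comparisons had 575 genes rising, where 67.8 would be shared by chance, and 546 falling, where 63.3 would be. Of the genes passing in both, 0 went in opposite directions. Chance counts here and for the pairs below take the comparisons as independent, although they share the wild-type reference strain. Shared wild-type RNA alone would give r = 0.50 by simulation of unchanged mutants. Same-numbered arrays deviated together more than that (0.86 to 0.89 across genes), so the simulation may understate what unchanged mutants would share. The simulated covariance was 0.00672 and the measured one 0.0725, with 0.0607 on opposite-numbered arrays. Between arrays of opposite dye the correlation was 0.68. K123R and ubp8 were correlated at r = 0.19 (rho = 0.17, covariance 0.00973), with 58 genes rising in both (12.6 by chance), 17 falling in both (6.07 by chance) and 24 in opposite directions. On arrays of opposite dye that correlation was −0.03. The 0.50 simulated for shared wild-type RNA is for unchanged mutants, so the r of 0.19 is not on the same scale. The covariance of 0.00973 lay above the simulated 0.00672, as did the 0.0116 of the double mutant with ubp8. The double mutant and ubp8 had r = 0.24 (rho = 0.20, covariance 0.0116), with 60 genes rising in both (11.4 by chance), 20 falling in both (6.02 by chance) and 22 opposite, and −0.0027 on arrays of opposite dye. Covariances were 0.0217 and 0.0235 on same-numbered arrays and −0.0022 and −1.5e-04 on opposite-numbered ones. The shared part of both pairs thus lies in arrays of the same number and dye. Their shared genes do not by themselves show a common response.

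**Figure D2:**
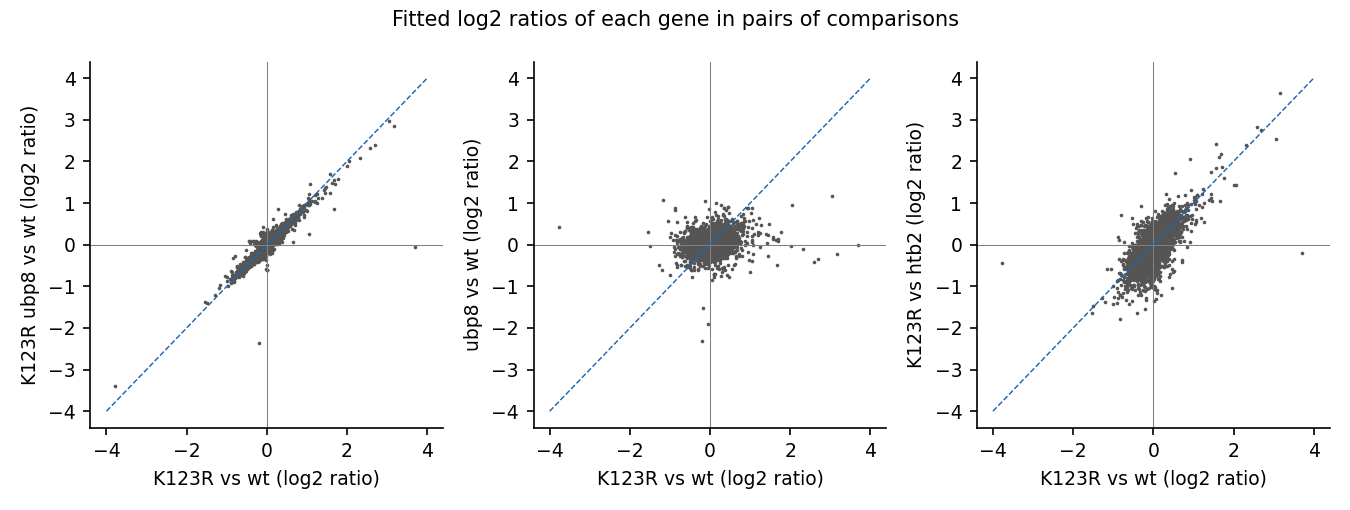
Fitted log2 ratio of each gene in K123R against wild type (x axis) and in the double mutant against wild type, ubp8 against wild type, and K123R against the htb2 deletion strain (y axes of the 3 panels), with equality dashed. Pearson r across genes was 0.95, 0.19 and 0.69 in turn.

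Compared through wild type, the double mutant and K123R differed in 0 of 6246 genes by limma, with 43 at an unadjusted p under 0.05. The genes with the smallest p were LEU2 (−3.75 ± 0.28, adjusted p = 0.0933), UBP8 (−2.16 ± 0.17, adjusted p = 0.0933) and the uncharacterised genes YIR043C (0.60 ± 0.07, adjusted p = 0.633), YEL075C (0.54 ± 0.08, adjusted p = 1.00) and YER189W (0.53 ± 0.08, adjusted p = 1.00). Since the deleted UBP8 itself did not pass, a count of 0 does not show that the strains were alike. The strains also differed in LEU2 signal, so this contrast does not isolate the loss of UBP8. A gene-specific dye term takes deviations shared by same-numbered arrays out of the spread, and with it the standard error of UBP8 was 0.12. In that fit, 9 genes were higher and 5 lower in the double mutant. Named after their values were seen, they include UBP8 (adjusted p = 0.00308), LEU2 (adjusted p = 0.00422), NFS1 (−0.79, adjusted p = 0.00308), the ORF YOR203W beside HIS3 (−0.81, adjusted p = 0.00308), and COS8 (0.48, adjusted p = 0.0143) and COS7 (0.41, adjusted p = 0.0143). Oxidative phosphorylation genes had a median of −0.10 and TCA cycle genes of −0.09 with 0 members passing in either (camera adjusted p = 2.8e-15 and 3.2e-06, adjusted p = 0.242 for each with an estimated correlation). Sulfur and methionine genes were higher in the double mutant in 24 of 25 cases, with a median of 0.08 (camera adjusted p = 4.7e-06, adjusted p = 0.316 with an estimated correlation). Genes near chromosome ends had a median of 0.01 (camera adjusted p = 4.5e-07, adjusted p = 0.123 with an estimated correlation) and COS genes of 0.04 (camera adjusted p = 1.2e-04, adjusted p = 0.442 with an estimated correlation). No member of these lists passed over all genes. Leaving out either K123R array or either ubp8 array gave 1 gene.

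K123R and ubp8 differed in 514 genes of 6246, 229 higher and 285 lower in K123R, and the double mutant and ubp8 in 413 of 6244, 173 higher and 240 lower in the double mutant. Apart from markers and deleted genes, HPF1 (3.03 ± 0.11, adjusted p = 0.00283), its relative CSS1 and ARG1 (2.43 ± 0.15) were highest in K123R relative to ubp8. CWP1 (−1.83 ± 0.30), the serine and threonine deaminase gene CHA1 (−1.76 ± 0.26), the ethyl ester synthesis gene EEB1 (−1.72 ± 0.07, adjusted p = 0.00283) and DIC1 (−1.62 ± 0.10) were lowest. Relative to ubp8, the double mutant had HPF1 at 2.73 ± 0.11, CSS1 at 2.74 ± 0.19 and EEB1 at −1.76 ± 0.07. PHO5 and PHO89, which fell in ubp8, were higher in K123R than in ubp8 by 1.33 (adjusted p = 0.0169) and 1.85 (adjusted p = 0.0231). They also passed in the double mutant relative to ubp8 (adjusted p = 0.024 and 0.0313, PHO89 at 1.74). Both were named here after their values were seen. Purine genes were higher in K123R than in ubp8, 5 of 13 (10 adjusted over the list alone), with a median of 0.88, camera adjusted p = 2.3e-06 and adjusted p = 0.505 with an estimated correlation. In the double mutant relative to ubp8 the same list had a median of 0.69 (camera adjusted p = 4.6e-05, adjusted p = 0.495 with an estimated correlation). The first count was 4 and 13 without K123R array 1 and array 2, 50 without either double mutant array, and 10 and 5 without ubp8 array 1 and array 2. The second was 49 without either K123R array, 3 without either double mutant array, and 6 and 5 without ubp8 array 1 and array 2. With a gene-specific dye term the counts were 3535 and 3443, and with median centring 330 and 226.

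The interaction, in which a value of 0 means that the double mutant equals the sum of the single mutants, passed in 0 of 6244 genes by limma, with 476 at an unadjusted p under 0.05 and 1337 with a gene-specific dye term (558 higher and 779 lower). The smallest p-values belonged to LEU2 (−3.73 ± 0.34, adjusted p = 0.249), EEB1 (−0.88 ± 0.08, adjusted p = 0.249), YAT1 (−0.87 ± 0.09, adjusted p = 0.249), FCY21 (−1.07 ± 0.12, adjusted p = 0.297) and PRM7 (−0.88 ± 0.10, adjusted p = 0.297), which did not pass. Genes of the stress response (median 0.32, camera adjusted p = 1.7e-10, adjusted p = 0.405 with an estimated correlation) and of ribosome assembly (median −0.20, camera adjusted p = 1.7e-10, adjusted p = 0.269 with an estimated correlation) were called with the sign opposite to that of both single mutants. An error in the shared wild type would enter the interaction with that same sign, so these calls do not separate it from a change in the mutants. Purine genes (median 0.40, camera adjusted p = 3.6e-07, adjusted p = 0.486 with an estimated correlation) had medians of 0.26 in K123R and −0.58 in ubp8. Sulfur and methionine genes (median 0.26, camera adjusted p = 1.9e-08, adjusted p = 0.405 with an estimated correlation) had 0.07 and −0.15. In none of these lists did a member pass over all genes. Leaving out either K123R array gave 1 gene.

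K123R against the htb2 deletion strain compares strains that both lack HTB2, so the lost gene copy is common to them. They differ in HIS3 as well as in the lysine. HIS3 apart, CSS1 (2.83 ± 0.08, adjusted p = 1.6e-04), HPF1 (2.75 ± 0.10, adjusted p = 2.1e-04) and COS12 (2.53 ± 0.08, adjusted p = 2.0e-04) were again the highest. They were followed by SNZ1 (2.42 ± 0.15) and ARG1 (2.39 ± 0.15), each from 1 array. A gene with 1 value has no residual spread of its own, so its standard error rests on the other genes. SNO1 (2.06 ± 0.09), SPR28 (1.86 ± 0.11) and MET17 (1.72 ± 0.08) also rose. The lowest were the mitochondrial pyruvate carrier gene MPC3 (−1.78 ± 0.09, adjusted p = 6.0e-04), the stress gene HSP12 (−1.65 ± 0.11) and CWP1 (−1.64 ± 0.16). Next were the histone H2A gene HTA2 (−1.55 ± 0.16), PNS1 (−1.47 ± 0.09), CMC1 (−1.44 ± 0.15), RGI1 (−1.39 ± 0.15) and BDH2 (−1.38 ± 0.08). UBP8 read −0.22 ± 0.08 (adjusted p = 0.0903). In all, 903 genes rose and 993 fell of 6109 tested, 36 and 51 by at least 2-fold, and 21 and 16 by that much on every array. The sign was the same on every array for 1677. Of the 1896, 1697 had values on 3 arrays, 156 on 2 and 43 on 1. Of these, 129 were called without a residual spread of their own, the 43 and 86 of the 156. For 113 of the called genes no dye term could be fitted, so a dye effect may enter their ratios.

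Of the 36 lists, camera called 13 here. This fit has 1 residual degree of freedom, which limits fry and the test with an estimated correlation: by fry 0 lists passed, and its smallest adjusted p was 0.155. In the fit against wild type, fry passed 17 lists in K123R, 7 in ubp8 and 15 in the double mutant. Amino acid synthesis genes rose in 25 of 37 cases with 1 falling (33 and 1 adjusted over the list alone), with a median of 0.52, camera adjusted p = 2.4e-18 and adjusted p = 0.885 with an estimated correlation. Sulfur and methionine genes rose in 15 of 23 cases with 1 falling (17 and 1 adjusted over the list alone), among them MET17, MET6 (0.93 ± 0.09) and SAM1 (0.81 ± 0.09), with camera adjusted p = 3.9e-07 (adjusted p = 0.885 with an estimated correlation). Purine genes rose in 10 of 13 cases (11 adjusted over the list alone), with ADE6 at 0.98 ± 0.14 and ADE3 at 0.79 ± 0.09, and 0 fell. Ribosome assembly genes rose in 36 of 72 cases (49 adjusted over the list alone), with RRP5 at 0.83 ± 0.10 and NOP2 at 0.81 ± 0.11, and 0 fell. Their camera adjusted p were 1.3e-04 and 4.3e-09 (adjusted p = 0.885 with an estimated correlation). Stress genes fell in 23 of 34 cases (26 down and 2 up adjusted over the list alone), with a median of −0.54 and with HSP12, PGM2 (−1.27 ± 0.09) and ALD3 (−1.13 ± 0.10) among them (camera adjusted p = 3.7e-12, adjusted p = 0.885 with an estimated correlation). Of 10 histone genes 8 passed with lower values (8 adjusted over the list alone), with a median of −0.90. One is HTB2 (−0.45 ± 0.09), which neither strain has, so its value is no fall in expression. Without it 7 of 9 fell, with a median of −0.93: HTA2, HHT1 (−1.34 ± 0.13), HHF2 (−1.21), HHT2 (−1.08 ± 0.11), HTA1 (−0.93 ± 0.16), HHF1 (−0.86) and HTB1 (−0.80 ± 0.09). HTA1 read −0.46 with saturated spots left out. Whether the probes tell apart histone genes of one kind, such as HHT1 and HHT2, was not tested, so the 7 values may not be separate readings. The median of all 10 was −1.02, −0.41 and −1.35 on arrays 1 to 3 (camera adjusted p = 4.4e-07, adjusted p = 0.885 with an estimated correlation). Genes of the G1 to S transition fell in 9 of 17 cases (11 adjusted over the list alone), with PCL1 at −0.77 ± 0.12 and CLN1 at −0.67 ± 0.10 (camera adjusted p = 0.00554, adjusted p = 0.885 with an estimated correlation). Ribosomal protein genes fell in 36 of 137 cases with 1 rising (35 and 1 adjusted over the list alone), with a median of −0.19 and RPL7B at −1.10 ± 0.10 (camera adjusted p = 9.9e-05, adjusted p = 0.885 with an estimated correlation). All 4 alpha-specific genes fell, with SAG1 at −1.15 ± 0.10 and STE3 at −0.85 ± 0.10 (4 adjusted over the list alone; camera adjusted p = 2.3e-04, adjusted p = 0.885 with an estimated correlation). Lists called against wild type did not all recur. Oxidative phosphorylation genes, which rose against wild type, had 2 members rising and 11 falling of 33 (2 and 11 adjusted over the list alone), with a median of −0.12 (camera adjusted p = 0.0545). Phosphate starvation genes had 2 rising and 2 falling of 15 (2 and 2 adjusted over the list alone), with a median of −0.02 (camera adjusted p = 0.966). The differences from the comparison with wild type were not tested. Transcripts of the mitochondrial genome had medians of −0.73, −0.14 and −1.28 on arrays 1 to 3. The count of 1896 was 504 without array 1, 2173 without array 2 and 978 without array 3, in fits that also dropped the dye term. Dropping that term alone gave 1854. Without array 2, K123R was in Cy3 on every array left, so dye and strain cannot be told apart there.

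Across 6108 genes the log2 ratios of K123R against wild type and against the htb2 deletion strain had r = 0.69 and rho = 0.65. In both, 400 genes rose (99.8 by chance) and 376 fell (101 by chance), and 20 passed in opposite directions. COS12, HPF1, CSS1, SPR28 and ARG3 rose and CWP1, PNS1, PGM2 and BDH2 fell in both. The double mutant against wild type had r = 0.71 with K123R against the htb2 deletion strain, and ubp8 against wild type had −0.01. No array is shared by these comparisons.

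**Figure D3:**
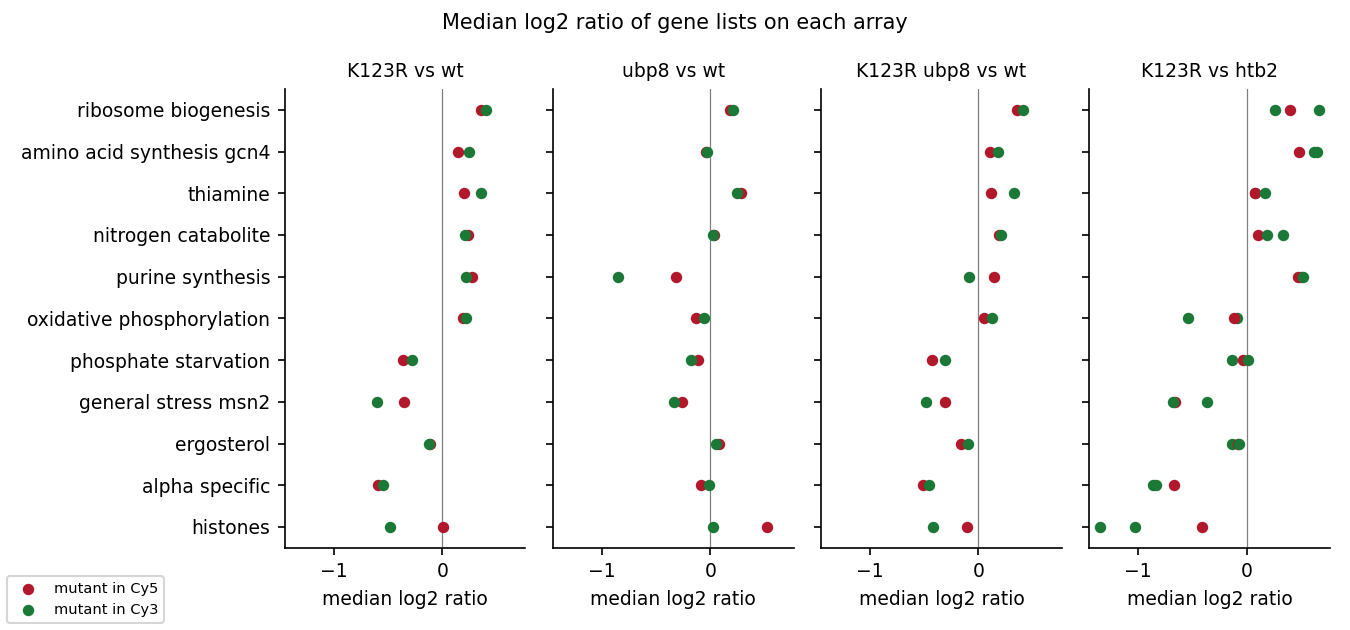
Median log2 ratio (x axis) of the members of 11 gene lists (y axis) on each array of the 4 direct comparisons, with the mutant in Cy5 in red and in Cy3 in green. Histone genes had medians of −1.02, −0.41 and −1.35 in K123R against the htb2 deletion strain, and 0.01 and −0.48 against wild type.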

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

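All tests in this part were chosen after the result was seen, except the test of shared wild-type RNA. K123R was compared with 2 reference strains, and among the genes named by the rule in either comparison, 8 that passed in at least one of them had one sign on every array against wild type and the opposite sign on every array against the htb2 deletion strain. Over all 6108 genes, 20 passed in opposite directions. Of the 8, SAM2 alone passed in both comparisons. The methionine synthase gene MET6 read −0.30 against wild type (adjusted p = 0.218) and 0.93 against the htb2 deletion strain (adjusted p = 0.00447), a difference of −1.23 that was not tested. SAM2, which makes S-adenosylmethionine, read −0.40 (adjusted p = 0.0119) and 0.46 (adjusted p = 0.0138), a difference of −0.86 that was not tested. The glucose transporter gene HXT4 read 0.48 (adjusted p = 0.128) and −0.65 (adjusted p = 0.0241), and the difference of 1.13 was not tested. The ribosomal protein gene RPL7B read 0.10 (adjusted p = 0.243) and −1.10 (adjusted p = 0.00394), and the difference of 1.198 was not tested. ATP7 of the ATP synthase read 0.40 (adjusted p = 0.00745) and −0.11 (adjusted p = 0.337), and the difference of 0.52 was not tested. For INO2, the activator of phospholipid synthesis, the values were −0.12 (adjusted p = 0.15) and 0.38 (adjusted p = 0.0421), and the difference of −0.49 was not tested. Of the mating genes, FUS2 read 0.22 (adjusted p = 0.0303) and −0.12 (adjusted p = 0.368), a difference of 0.35 that was not tested. FIG1, also a mating gene, read 0.30 (adjusted p = 0.0475) and −0.13 (adjusted p = 0.406), a difference of 0.43 that was not tested.

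LEU2 was high in K123R on the 2 arrays against wild type and low in K123R on the 3 arrays against the htb2 deletion strain. A dye or spot artefact is argued against by the 2 arrays of opposite dye, the lower of which read 3.27. A swap with the double mutant RNA is argued against by UBP8, whose lower value on these arrays was −0.28. The neighbouring gene NFS1 read at least 0.98 on both arrays and rose by 1.06 ± 0.09 (adjusted p = 0.00396), which a DNA segment with LEU2 in the cells used could give, but NFS1 also rose against the htb2 deletion strain (0.60 ± 0.08, adjusted p = 0.00855), where LEU2 was low. In the double mutant NFS1 (0.27 ± 0.09, adjusted p = 0.109) was not below the set bound on both arrays, so this explanation and a different K123R isolate cannot be told apart.

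Same-numbered arrays of the 3 comparisons with wild type deviated from their pair in the same genes, with correlations of 0.89, 0.86 and 0.87 across genes. A gene-specific dye effect may be one source, since the mean deviation had r = 0.53 with the dye term of the arrays against the htb2 deletion strain (5654 genes). After regression on that term the lowest of the 3 correlations was 0.83, above the bound set for wild-type RNA shared by same-numbered arrays. It also exceeds the r = 0.50 simulated for unchanged mutants that share wild-type RNA, so sharing alone may not account for it. A dye effect particular to these 6 arrays could raise it too, and the array number and the dye change together in this design.

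Histone genes were lower in K123R against the htb2 deletion strain, with a list median of −0.90, or −0.93 without HTB2, which neither strain has. A dye effect large enough to give the whole fall is argued against by the 3 arrays, the highest of which had a median of −0.41. That was array 2, the only one with K123R in Cy5. Against wild type, the list median also read lower with the mutant in Cy3 than in Cy5. The values were −0.48 and 0.01 in K123R, 0.03 and 0.52 in ubp8, and −0.42 and −0.11 in the double mutant. A dye contribution to the size is left open. Saturated spots are argued against by the median of −0.85 with such spots left out, over 10 members (−0.86 without HTB2), though HTA1 went from −0.93 to −0.46. Fewer cells in S phase may contribute: genes of the G1 to S transition had a median of −0.35 and were called downward (camera adjusted p = 0.00554, adjusted p = 0.885 with an estimated correlation), and genes of the G2 to M transition were not called (camera adjusted p = 0.103). In K123R against wild type, the histone list without HTB2 was not called (median −0.19, camera adjusted p = 0.569). The G1 to S list was not called there either (median −0.13, camera adjusted p = 0.0887). The pattern was thus called against one reference strain only, and the difference between the comparisons was not tested. Fewer cells in S phase stays a hypothesis, since cell cycle stage was not measured here and it was found and tested on the same data.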

How the results depend on the processing

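The counts of genes depend on how the spread between arrays is modelled. Named genes that passed kept their direction, but the choice of genes largely fixed this. The highest and lowest had to have the same sign on every array. So did all 1318 genes called in K123R and all 175 called in ubp8 against wild type, so leaving out an array could not reverse them. Of 396 passing values of named genes (217 different genes, some in several comparisons), 0 reversed and 115 passed under every alternative run; of 6449 alternative values, 5502 kept their side of the threshold and 947 no longer passed. With the array number as a replicate block, the paired form of the fit (a gene-specific dye term), the counts were 4137 in K123R, 3119 in ubp8 and 4083 in the double mutant against wild type, 14 for the double mutant against K123R, 3443 for the double mutant against ubp8, 3535 for K123R against ubp8 and 1337 for the interaction. With the slide as a random block they were 5230, 4702, 5152, 3011, 4976, 4737 and 4770. That fit used red over green ratios, where the shared dye effect also enters, and no slide holds both arrays of a comparison with wild type. Under it the uncalled MF(ALPHA)2 in ubp8 (0.071) and ADE2 in the double mutant (0.16) changed sign and passed. A further 4 uncalled values of named genes changed sign without passing. For ubp8 the count was 91 with Agilent processed signals and 85 with the deposited values, and median centring gave 226 for the double mutant against ubp8 and 330 for K123R against ubp8. On arrays of opposite dye the correlation was 0.68 for K123R with the double mutant, −0.033 for K123R with ubp8 and −0.0027 for the double mutant with ubp8. Leaving out each array in turn, with a lone array assumed to vary like the other groups, gave 34 to 884 genes in K123R, 0 to 8 in ubp8 and 3 to 823 in the double mutant against wild type, 0 to 1 for the double mutant against K123R and for the interaction, 3 to 49 for the double mutant against ubp8, 4 to 50 for K123R against ubp8, and 504 to 2173 in K123R against the htb2 deletion strain. The fits that left out an array against the htb2 deletion strain also dropped the dye term, so their counts reflect both changes. The 2173 came without array 2, where dye and strain cannot be told apart. Fits to only the 2 arrays of a comparison gave 1124 in K123R, 237 in ubp8 and 1188 in the double mutant against wild type. For these changes the cause was not tested. The slide block for the htb2 arrays could not be fitted with the dye term, and the brightest probe per gene was not run since each gene had 1 probe. Keeping outlier-marked spots, leaving out saturated spots and leaving out the third htb2 array were chosen after seeing the data. Signal over background, 25.8 to 54.6 in green, limits ratios of genes near background in the reference strain, such as deleted markers.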

Other observations

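COS12 stood apart from its family. In K123R against wild type COS9 (−0.56 ± 0.10, adjusted p = 0.0169), COS6 (−0.37 ± 0.07, adjusted p = 0.0219) and COS4 (−0.19 ± 0.05, adjusted p = 0.0488) fell while COS12 rose, so the list had a median of −0.14 and a mean of 0.11 and was not called (camera adjusted p = 0.941). Against the htb2 deletion strain 6 of 12 COS genes fell and 1 rose, with a median of −0.47 (camera adjusted p = 0.505). COS8 rose in ubp8 (0.71 ± 0.10) and in the double mutant (0.63 ± 0.10, adjusted p = 0.016) and read 0.14 ± 0.10 in K123R (adjusted p = 0.388). RSC30, YHR054C and the metallothionein genes CUP1-1 and CUP1-2 are neighbours (assembly R64), and these genes were grouped after their values were seen. Whether their probes tell these genes apart was not tested, so their values may not be separate readings. RSC30 read 0.44 ± 0.07 in K123R, 0.90 ± 0.07 in ubp8 and 0.43 ± 0.07 in the double mutant. YHR054C read 0.45 ± 0.08, 0.91 ± 0.08 and 0.43 ± 0.08. CUP1-1 read 0.34 ± 0.11 in K123R (adjusted p = 0.0819), 0.89 ± 0.11 in ubp8 and 0.21 ± 0.11 in the double mutant (adjusted p = 0.239).

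Iron genes fell in 5 of 24 cases in K123R against wild type (6 adjusted over the list alone), among them the siderophore transporter gene ARN2 (−0.65 ± 0.06, adjusted p = 0.00465), FRE3 (−0.58 ± 0.05) and MRS4 (−0.51 ± 0.07), but the list was not called (camera adjusted p = 0.0887). The DNA damage list was called in ubp8 with 2 of 11 rising (5 up and 1 down adjusted over the list alone), led by RNR3 (0.53 ± 0.05). Its camera adjusted p was 0.0147 and the adjusted p with an estimated correlation was 0.399. RNR3 also rose in K123R (0.38 ± 0.05) and RNR1 fell (−0.45 ± 0.07, adjusted p = 0.0152). Of the enzymes acting on K123, RAD6 rose in K123R (0.38 ± 0.05, adjusted p = 0.00767), and BRE1 read 0.20 ± 0.06 (adjusted p = 0.0646). The list of H2B ubiquitylation and H3 methylation genes was not called (camera adjusted p = 0.744). SAGA genes were not called in K123R either (camera adjusted p = 0.994), though SPT7 (0.38 ± 0.05) rose and SPT3 (−0.38 ± 0.07) fell. Transcripts of the mitochondrial genome had medians of 0.21, −0.10 and 0.12 in K123R, ubp8 and the double mutant against wild type and −0.53 in K123R against the htb2 deletion strain. The medians of the 16 nuclear chromosomes lay between −0.03 and 0.05.

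The Leu3 test was chosen after LEU1 and OAC1 had been seen, and the chromosome-end tests and the test of other array assignments before their results were seen. High LEU2 could raise leucine and so lower the targets of the regulator Leu3 in K123R relative to the double mutant. All 9 targets were lower in K123R on both arrays, but the median differences were −0.12 and −0.13, short of the size set for the hypothesis. LEU1 (−0.45 and −0.59), OAC1 (−0.44 and −0.59) and BAT1 (−0.27 and −0.50) differed most. OAC1 was higher in the double mutant with a gene-specific dye term (adjusted p = 0.0189), and LEU1 was not called with it (adjusted p = 0.188). A smaller effect is left open.

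Genes within 20 kb of a chromosome end could rise as a set when K123 is lost, but the list was not called in K123R against wild type (camera adjusted p = 0.269) or against the htb2 deletion strain (0.478). It was called in the double mutant (camera adjusted p = 0.0079, adjusted p = 0.299 with an estimated correlation). Members brighter than the median gene had medians of −0.13 and −0.15 over 64 and 68 genes, against −0.0075 and −0.0084 in the other bright genes. The one-sided permutation p for being higher was 0.9997 and 0.9956, so bright members lay lower than other bright genes, not higher. Any higher values near chromosome ends were thus not seen in bright members as a set, and may come with low signal. Members outside the repeated families had medians of 0.01 and 0.0032 over 204 and 201 genes (permutation p = 0.261 and 0.237). An effect of probes reading repeated families together cannot be told apart from a change in single genes, because these medians lie near 0.

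K123R against the htb2 deletion strain was also fitted with the strains assigned to the colours in other ways. There are 3 assignments, too few for a share under 0.05; the real one called 1896 genes, the highest other 0, and 1 called as many as the real one, itself.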
